A study of Arabidopsis thaliana with 41 samples.

How the data were processed

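Rosette leaf RNA of Arabidopsis thaliana was measured on 41 oligonucleotide arrays. The arrays cover 7 natural accessions (Bil-5, Eden-1, Got-22, Omo2-3, Tamm-2, Ull2-5 and Ag-0), each grown at 2 soil water levels. Per the labels' protocols, plants grew 1 per pot in about 150 ml of a porous ceramic medium, with a 10 h photoperiod at a photon flux density of 330 µmol per square metre per second, 23 °C by day, 18 °C by night and 60% relative humidity. Dry pots lost water stepwise, under daily weighing, until about 50% of the available water remained, and wet pots were held near 90%. Leaves were collected into a stabilising solution, total RNA was column purified, and biotin-labelled cRNA was hybridised, per the labels' protocols. The series' design text calls the replicates biological. Other accessions of the design are not analysed here.

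The authors deposited 1 value per locus and array on a log2 scale; the log2 unit was inferred from the values themselves, which ran from 3.35 to 14.30 with array medians between 5.66 and 5.79. RMA and MAS5 are named in the submitters' processing notes, without their roles or versions. The array design's probe filter, the genome build, and whether probes with sequence differences between accessions were removed are not given in the sources used here. Accessions carry sequence differences from the reference strain, so a low value of a locus in an accession can come from poor hybridisation as well as from low expression. An array value has no count behind it, and the number of arrays limits the precision.

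The table held 21164 loci, of which 21085 were nuclear, 76 mitochondrial and 3 plastid, and 0 columns belonged to other samples. Symbols were taken from a gene table of assembly TAIR10.1, in which 20972 loci matched. The table was used for names only; in 1 test of neighbouring loci their distance was taken from the locus numbers, which follow the order along a chromosome. Values of 26 loci were identical to those of another locus on every array and are not separable from it. No locus was removed and no further normalization was applied.

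Each comparison used 1 linear model with a mean for each of the 14 combinations of accession and soil water, fitted over all 41 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 27 residual and 2.06 prior degrees of freedom). All groups thus shared 1 estimate of the spread. The drying effect was the mean over the 7 accessions of dry minus wet, each accession weighted equally. Drying was also tested within each accession. Moderated F tests with 6 numerator degrees of freedom asked whether the 7 drying changes were equal (the interaction) and whether the 7 accession means over both water levels were equal (the accession effect), and each accession was set against the mean of the other 6. P-values were two-sided and adjusted by Benjamini-Hochberg over all loci, with a threshold of 0.05. Standard errors of log2 changes come from that model, and an SD given with a mean of all dry or wet arrays includes differences between accessions.

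Gene lists were fixed from textbook knowledge before the data were examined: 23 lists with 417 loci, of which 374 were measured. They were tested on the drying effect with camera at a preset correlation of 0.01 and again with an estimated correlation. Each list was also scored on every array as the mean log2 value of its members. Drying was tested on these scores by permuting soil water within accessions (100000 permutations, two-sided), and the interaction by permuting the residuals of the additive model (100000 permutations); both were adjusted over the 23 lists. Enrichment of a list among accession-effect genes was tested with Fisher's exact test against all other measured loci, adjusted over the 23 lists.

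Genes named in the text follow a rule fixed at the same time. For drying these were the 12 largest rises and 12 largest falls among genes past the threshold with the same sign in all 7 accessions, and within each accession the 3 largest rises and falls. For the interaction and accession F tests they were the 15 smallest p-values past the threshold, and for each accession the 2 highest and 2 lowest loci against the other 6. From each list up to 4 members with the smallest p were taken; other list members named below were chosen after their values were seen. RD29A, RD29B, RAB18, NCED3, HAI1, COR15A, FLC and FRI are named whatever their value; P5CS1, also on that list, is not analysed here.

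Alternatives chosen before the data were examined were quantile normalization, centring of each array on its median, removal of the lowest 25% of loci, eBayes with a trend and robust prior, array quality weights, replicate number as a block, an additive model, fold and range filters, fits of single accessions, wet arrays only, and leaving out each array or accession. Added after the data were seen were fits without the 3 arrays of quality weight under 0.5, and without Bil-5 for the accession effect and the list scores. Methods were tested on simulated data: with the real spread of each locus, the drying test called 99 of 100 loci changed by 1 log2 unit, 90 of 100 changed by 0.5, and 27 of 20549 unchanged loci. In the same simulation the interaction test called 194 of 200 loci changed by 3 log2 units in 1 accession and 20 of 20764 unchanged loci, the accession test 198 of 200 shifted by 2 and 26 of 20564 unchanged, and the test within 1 accession 194 of 200 changed by 2. All accessions were simulated with the same spread at a locus. Deviations of the real arrays from their group mean had an SD of 0.147 (Omo2-3 dry replicate 2) to 0.418 (Bil-5 dry replicate 3). How the tests do under such unequal spread was not simulated. Camera called the 1 shifted list and 0 of 22 unchanged lists. Simulated loci varied independently, whereas camera's estimated correlation was 0.37 for the real starch list and 0.81 for photosynthesis. These list counts therefore say nothing about lists whose members vary together. The permutation test of neighbouring loci gave p = 5e-04, the smallest its permutations can give, with shared patterns and p = 0.883 without. In the simulation with shared patterns every locus shared a strong pattern with its neighbours. How the test does with weak sharing was not simulated. Figures were drawn with matplotlib 3.10.9.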

Results

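Leaf transcript levels were measured at 21164 loci in 7 accessions under slow soil drying and under continued watering. Each group held 3 arrays, except dry Ag-0 with 2, which gave 20 dry and 21 wet arrays. Correlation of an array with the others of its group averaged between 0.951 (Bil-5 dry replicate 3) and 0.991. The 3 arrays with a quality weight under 0.5 were Bil-5 dry replicate 3 (0.271), Tamm-2 dry replicate 3 (0.327) and Bil-5 wet replicate 2 (0.360). The crossed design asks what mild drying changes in leaves, which transcripts differ between accessions whatever the watering, and whether accessions respond differently.

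Among loci with the same sign in all 7 accessions, the largest mean changes under mild drying were rises of AT3G53980 and LTP4 and a fall of PDF1.2A. LTP4 had a log2 signal of 9.51 ± 1.41 (SD, n = 20) on dry arrays and 6.51 ± 1.85 (SD, n = 21) on wet arrays, a rise of 3.04 ± 0.41 (SE). AT3G53980 (3.31 ± 0.35), AT2G37870 (2.92 ± 0.28) and AT4G33550 (2.54 ± 0.36), of the same lipid-binding superfamily, also rose. PDF1.2A, a defensin induced by jasmonate and ethylene, changed by -2.92 ± 0.60, from 9.51 ± 2.97 on wet arrays to 6.72 ± 2.96 on dry arrays. Limma's adjusted p was 4.73e-06 for LTP4 and 0.000574 for PDF1.2A.

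The other large rises included the sugar transporter-like AT5G18840 (2.04 ± 0.36), SRO5 (1.46 ± 0.22), DAA1 (1.44 ± 0.18), AT4G16146 (1.43 ± 0.27) and AT2G34510 (adjusted p = 4.17e-07). PnsB3, a subunit of the chloroplast NDH complex, rose by 1.38 ± 0.21, and AT4G23670 and AT2G36145 rose by 1.38 ± 0.25 and 1.36 ± 0.19. Among the falls were MEE3, a MYB-like factor (-2.20 ± 0.27), AT1G21520 (-2.18 ± 0.22), AT1G72060 (-2.11 ± 0.33), the beta-galactosidase gene BGAL4 (-2.05 ± 0.50) and AT2G43620 (-2.03 ± 0.28). The cell wall invertase gene ATBFRUCT1 changed by -1.95 ± 0.27, and AHP4, of the cytokinin phosphorelay, by -1.95 ± 0.30. AT3G22060 (-1.93 ± 0.36), PRA1.F1 (-1.82 ± 0.22), AT5G61160 (-1.81 ± 0.32) and KCS12, of very-long-chain fatty acid synthesis (-1.75 ± 0.35), completed the set. All 24 had the same sign in each of the 7 accessions, as the rule required, and limma's adjusted p among them was at most 0.00292, for BGAL4. Some sizes are not exact, since AT4G33550 and DAA1 lay near the array floor on wet arrays of most accessions, AT5G61160 on dry arrays of most, and PDF1.2A in Ag-0 and on dry arrays of Bil-5 and Tamm-2.

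**Figure D1:**
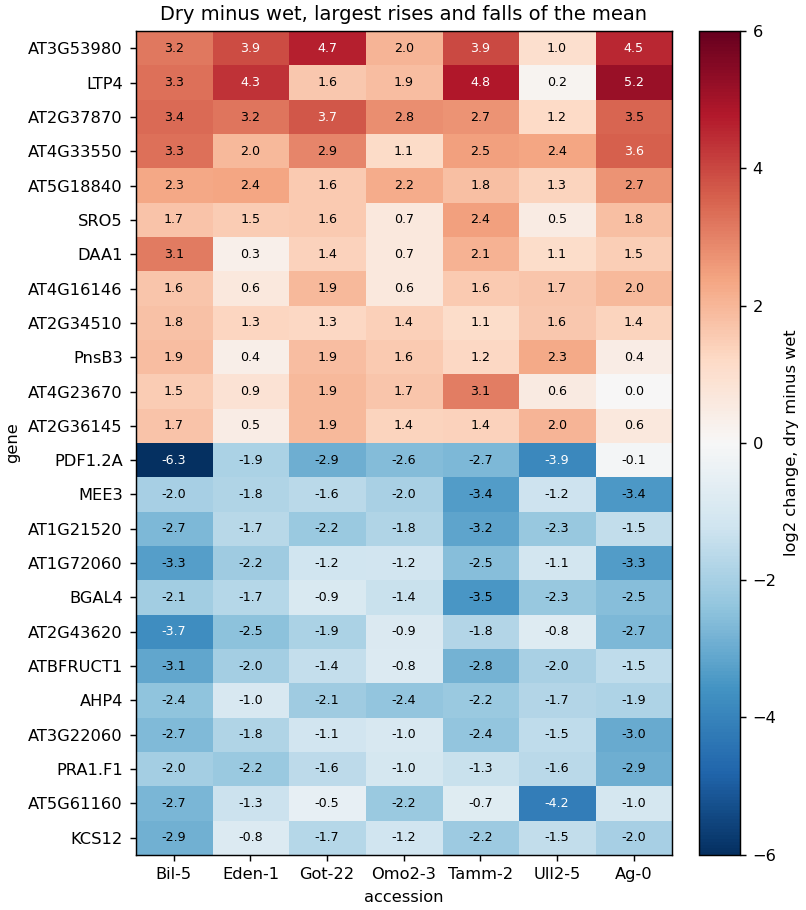
Log2 change (dry minus wet) in each of the 7 accessions (columns) for the 12 largest rises and 12 largest falls of the mean change (rows); colour and printed number give the change. Every cell of a row has the same sign, and LTP4 ranges from 0.16 in Ull2-5 to 5.19 in Ag-0.

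Over all loci, limma called 2582 that rose and 2442 that fell (23.7% of those tested), 1685 and 1337 of them with the same sign in all 7 accessions. Changes were small: the median absolute log2 change of called loci was 0.34, and 54 loci rose and 113 fell by at least 1 log2 unit. Without the 3 arrays of low quality weight, a setting chosen after seeing the data, 2788 rose and 2566 fell, and 4681 of these calls were shared, with the same sign, with the 5024 over all arrays.

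Genes of starch metabolism rose together. Of 14 measured, 11 rose and 0 fell (11 rose adjusted over the list alone), with a mean log2 change of 0.60. They covered both making and breaking starch: APL3, of ADP-glucose pyrophosphorylase (1.22 ± 0.37), the granule-bound starch synthase GBSS1 (1.07 ± 0.33) and SS1 (0.51 ± 0.09) rose, as did the phosphoglucan phosphatase SEX4 (1.18 ± 0.21), the glucan water dikinase SEX1 (0.67 ± 0.13), the beta-amylase BAM3 (0.52 ± 0.11) and the disproportionating enzyme DPE2 (0.73 ± 0.15). BAM1 differed by 0.26 ± 0.16 and did not pass limma's threshold (adjusted p = 0.294), nor did SS3 and BAM5. The list was called by camera (adjusted p = 7.68e-06), but adjusted p = 0.277 with an estimated correlation; by permutation of soil water over the array scores its adjusted p was 0.00046.

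Genes of salicylic acid and defence fell. Of 23 measured, 0 rose and 12 fell (16 fell adjusted over the list alone), with a mean log2 change of -0.50. ICS1, the main enzyme of salicylic acid synthesis, changed by -0.81 ± 0.15, EDS5, which exports its product from the chloroplast, by -0.71 ± 0.12, PAD4 by -0.77 ± 0.20, and the marker gene PR1 by -1.18 ± 0.41; PR2 fell too (limma adjusted p = 0.0242). FMO1, of the N-hydroxypipecolic acid pathway, changed by -0.68 ± 0.11, and ALD1, of the same pathway, by -0.28 ± 0.07; without Eden-1 both calls ended (limma adjusted p = 0.0836 and 0.185). Camera's adjusted p for the list was 4.15e-06, with adjusted p = 0.277 with an estimated correlation, and the permutation of array scores gave an adjusted p of 0.00115.

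Leaf senescence genes fell in part. Of 14 measured, 0 rose and 6 fell (6 adjusted over the list alone), with a mean log2 change of -0.56. The NAC factors NAP and ORE1, which promote senescence, changed by -1.48 ± 0.19 and -1.28 ± 0.21, WRKY6 by -0.65 ± 0.09 and SAG21 by -0.56 ± 0.12. SAG12, a late senescence marker, lay near the array floor, with a mean of 3.97, and differed by 0.09 ± 0.06 (limma adjusted p = 0.304). Camera's adjusted p was 0.00205, with adjusted p = 0.277 with an estimated correlation, and permutation of array scores gave an adjusted p of 0.0015.

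All 4 genes of phloem and vasculature fell: the sucrose transporter SUC2 (-0.32 ± 0.09), the phloem identity factor APL (-0.34 ± 0.08), and the sucrose exporters SWEET11 (-0.39 ± 0.14) and SWEET12 (-0.72 ± 0.23). Camera's adjusted p was 0.0182, with adjusted p = 0.277 with an estimated correlation, and permutation gave an adjusted p of 0.00115. SWEET12 lost its call without Bil-5 (limma adjusted p = 0.0645) and SUC2 without Omo2-3 (0.0624) or Tamm-2 (0.0708). SWEET11 lost it without Bil-5 (0.0895), Got-22 (0.135), Omo2-3 (0.109), Tamm-2 (0.0610) or Ull2-5 (0.0546), and without any of 17 single arrays, with 0.0749 at the highest for Ag-0 dry replicate 2. Lists of other cell types did not pass, and whether they differed from the phloem list was not tested: of 10 root markers 0 rose and 0 fell (camera adjusted p = 0.968), of 12 guard cell and stomatal lineage genes 0 rose and 1 fell (FAMA, -0.15 ± 0.04, with limma adjusted p = 0.0799 without Ag-0; camera adjusted p = 0.961), and of 14 genes of dividing cells 1 rose and 0 fell. The riser was the D-type cyclin CYCD3;1 (1.26 ± 0.23), and that list's camera adjusted p was 0.961. Group means of the root list were 4.61 to 4.83, near the array floor. Those of the guard cell list (4.83 to 5.13) and the dividing cell list (4.86 to 5.33) were also low, against 8.22 to 9.33 for phloem. This limits the falls that could be seen in these lists, so they do not show that the fall was particular to phloem.

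**Figure D2:**
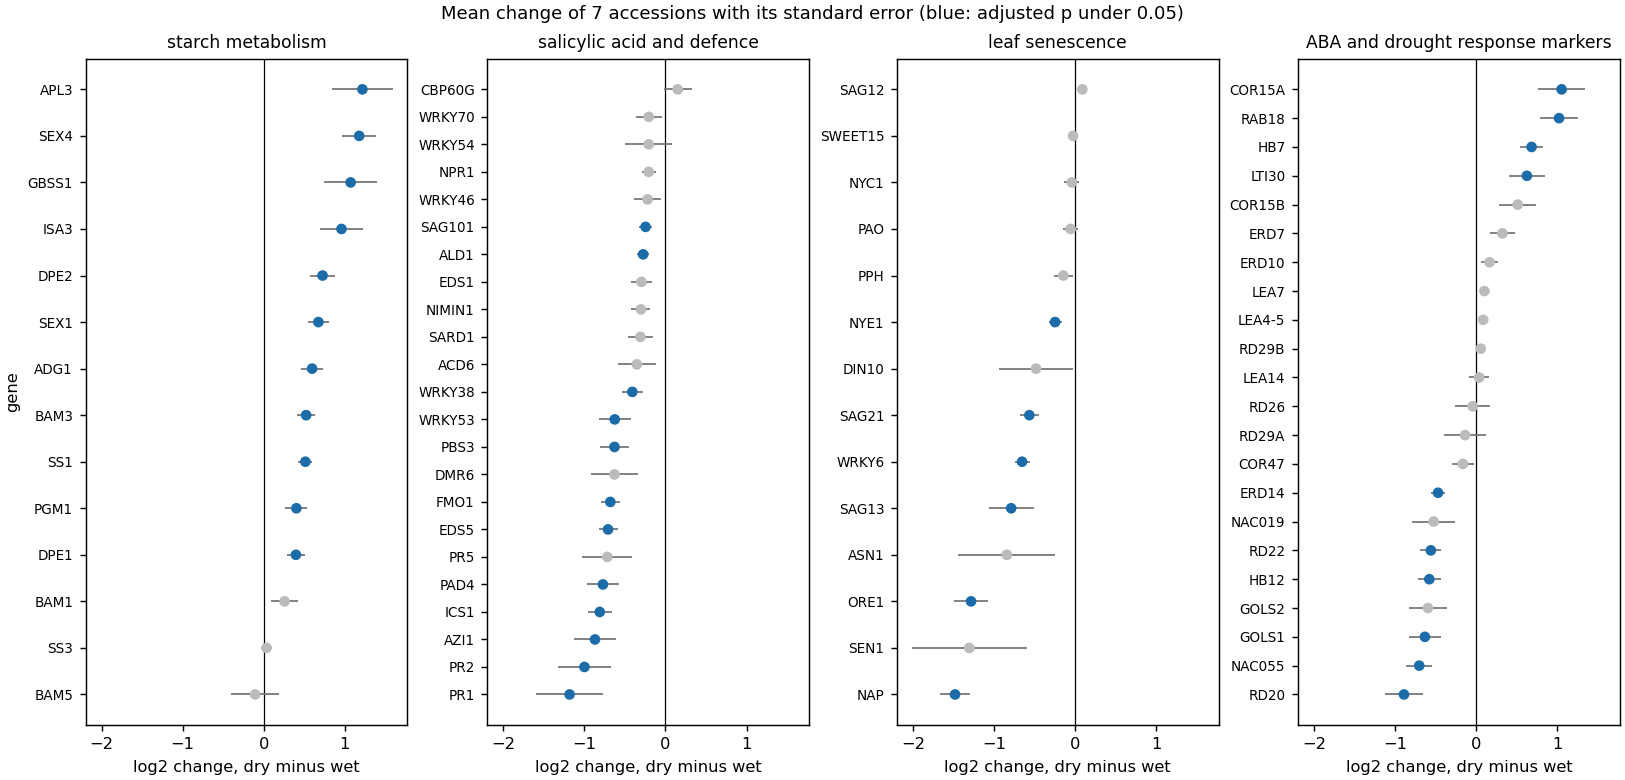
Mean log2 change over the 7 accessions (dry minus wet, horizontal axis) of each measured member of 4 lists, with bars of 1 SE; blue points passed limma's adjusted threshold and grey points did not. Starch members lie between -0.11 (BAM5) and 1.22 (APL3), and abscisic acid markers spread on both sides of 0.

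Abscisic acid and drought response markers moved both ways. Of 22 measured, 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.961). The dehydrin RAB18 rose by 1.02 ± 0.23 and the cold- and drought-induced COR15A by 1.06 ± 0.29 as means over accessions, though neither passed within any single accession, while RD20 changed by -0.89 ± 0.24, NAC055 by -0.70 ± 0.16 and ERD14 by -0.47 ± 0.09. RD29A, a common reporter of osmotic stress, stood at 9.70 ± 1.33 (SD, n = 21) on wet and 9.59 ± 1.22 (SD, n = 20) on dry arrays (limma adjusted p = 0.778), and RD29B differed by 0.06 ± 0.05 (limma adjusted p = 0.464). Of 16 genes of abscisic acid synthesis, breakdown and transport, 3 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.936): the catabolic CYP707A1 rose by 0.46 ± 0.09, and AAO3, of the last step of synthesis, changed by -0.57 ± 0.10. NCED3, the stress-induced step of synthesis, differed by 0.27 ± 0.18 (limma adjusted p = 0.310).

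Abscisic acid receptors and phosphatases were tested as 2 lists, and a difference between them was not tested. Of 10 receptors 0 rose and 4 fell, among them PYL6 (-0.74 ± 0.17) and PYL8 (-0.48 ± 0.12); camera did not call the list (adjusted p = 0.0916), and the permutation of array scores did (adjusted p = 0.00662). Of 9 clade A phosphatases 2C, negative regulators of the same pathway, 3 rose and 1 fell: PP2CA (0.93 ± 0.10), HAI2 (0.62 ± 0.14) and HAI1 (0.28 ± 0.06) rose and HAB1 changed by -0.38 ± 0.13 (3 and 2 adjusted over the list alone; camera adjusted p = 0.848). HAB1 lost its call without any of 6 single arrays (limma adjusted p = 0.0576 at the highest, without Ag-0 dry replicate 3) and without Eden-1 (0.0948), Got-22 (0.0586), Omo2-3 (0.0995), Tamm-2 (0.0584) or Ull2-5 (0.0696). PYL7, another receptor that fell, lost it without Ag-0 dry replicate 2 (0.0549), Eden-1 (0.0669) or Tamm-2 (0.0694). Of 6 genes of proline metabolism 1 rose and 2 fell (camera adjusted p = 0.848): the catabolic P5CDH rose by 0.44 ± 0.08, and PDH2, a proline dehydrogenase, changed by -1.04 ± 0.19. The permutation of array scores did not call the proline list (adjusted p = 0.224) but did without Ag-0 (0.0299).

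The photosynthesis list passed 1 of 3 tests. Of 30 measured, 5 rose and 1 fell (3 and 0 adjusted over the list alone), with a mean log2 change of 0.16; PSBO2 (0.71 ± 0.16) and PSBO1 (0.28 ± 0.09), of the oxygen-evolving complex, and LHCB6 (0.30 ± 0.11) rose, and LHCB4.3 changed by -0.23 ± 0.09. PSBO1 lost its call without Got-22 (limma adjusted p = 0.0782). Camera called the list (adjusted p = 0.00466), with adjusted p = 0.124 without Got-22 and 0.98 with an estimated correlation, and the permutation test did not (adjusted p = 0.224). Of 16 aquaporins 1 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0923): PIP1;4 rose by 0.67 ± 0.13, and PIP1;5 and TIP1;1 changed by -0.70 ± 0.16 and -0.54 ± 0.14. TIP1;1 lost its call without Ag-0 (-0.37, limma adjusted p = 0.0757). Of 24 genes of cell wall loosening 4 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.961), with XTH22 up by 0.51 ± 0.09 and XTH7 at -0.79 ± 0.18.

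Jasmonate and auxin genes changed member by member. Of 21 jasmonate genes 2 rose and 6 fell (camera adjusted p = 0.519): ORA59, an ERF factor that activates PDF1.2A, changed by -1.75 ± 0.20 and the repressor JAZ12 by -0.61 ± 0.08, while JAZ7 rose by 1.24 ± 0.33. Of 15 auxin response genes 0 rose and 4 fell, among them GH3.3 (-0.97 ± 0.17) and IAA7 (-0.65 ± 0.14), with 1 and 5 adjusted over the list alone. GH3.5 also fell and lost its call without Ag-0 dry replicate 3 (limma adjusted p = 0.0665), Got-22 (0.124), Bil-5 (0.0915) or Omo2-3 (0.0733). Camera's adjusted p for the auxin list was 0.0827, and the permutation test gave an adjusted p of 0.0485, which ended with members scaled to unit SD (0.181) and without Ag-0 (0.0709) or, in a setting chosen after the data were seen, Bil-5 (0.104). The mean, the median and camera's direction differed in sign for some lists: the jasmonate mean was -0.13 with a median of 0.02, the cell wall mean -0.03 with a median of 0.05 and camera's direction up, and the guard cell mean 0.03 with camera's direction down. Lists given without a drying count adjusted over the list alone had the same drying counts either way.

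Within single accessions LTP3 rose by 3.92 ± 0.91 in Bil-5, 4.68 ± 0.91 in Tamm-2 and 4.52 ± 1.02 in Ag-0, and LTP4 by 4.81 ± 1.07 in Tamm-2 and 5.19 in Ag-0. AT3G53980 rose by 4.66 ± 0.90 in Got-22, 3.94 ± 0.90 in Tamm-2 and 4.53 ± 1.01 in Ag-0. AT2G37870 rose by 3.41 ± 0.73 in Bil-5, 3.19 ± 0.73 in Eden-1 and 3.71 ± 0.73 in Got-22; AT4G33550 rose in Bil-5 too (limma adjusted p = 0.0384). MEE3 changed by -3.37 ± 0.70 in Tamm-2 and -3.45 ± 0.78 in Ag-0, and PDF1.2A by -6.31 ± 1.57 in Bil-5. PDF1.2A lay near the array floor on the dry Bil-5 arrays, so the size of its fall there is not exact. These values rest on 3 dry and 3 wet arrays, or 2 and 3 in Ag-0.

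Other changes also ranked among the largest of an accession; whether they differed between accessions was tested by the interaction only. In Eden-1, FMO1 changed by -3.26 ± 0.30, the camalexin enzyme gene CYP71A13 by -2.88 ± 0.58 and AT3G13610 by -2.53 ± 0.36, while AT4G25790 and the metal transporter gene NRAMP6 rose by 1.74 ± 0.39 and 1.67 ± 0.29. In Bil-5, AT2G25510 and AT2G43620 changed by -4.05 ± 0.90 and -3.71 ± 0.72, with SE from the spread shared by all groups. Neither passed in limma on the Bil-5 arrays alone (adjusted p = 0.516 and 0.162). AT2G25510 read 4.61 on Bil-5 dry replicate 3, against 11.38 and 11.09 on the other dry arrays. Without that replicate its change was -1.84 (limma adjusted p = 0.00886). In Got-22, AT5G45630 rose by 1.61 ± 0.33, and AT1G23040, SAUR63 and NDB3 changed by -1.44 ± 0.25, -0.88 ± 0.17 and -0.80 ± 0.15; without Got-22 wet replicate 2 the SAUR63 change was -0.54 and did not pass (limma adjusted p = 0.202). In Ull2-5, PnsB3 rose (limma adjusted p = 0.0310), AT2G36145 and AT5G45630 rose by 2.02 ± 0.50 and 1.95 ± 0.33, and AT5G61160, AT1G59950 and AT1G26380 changed by -4.17 ± 0.83, -3.28 ± 0.33 and -3.16 ± 0.49. AT5G39520 and AT1G21520 changed by -3.35 ± 0.80 and -3.16 ± 0.58 in Tamm-2, and AT3G16670 and PRA1.F1 by -4.30 ± 0.95 and -2.92 ± 0.63 in Ag-0. Changes of SAUR63 and NDB3 in Got-22, AT4G25790 in Eden-1, and AT5G45630 and AT1G26380 in Ull2-5 are not exact in size, since one side lay near the array floor.

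Limma called 606 loci that rose and 282 that fell in Bil-5, 20 and 43 in Eden-1, 12 and 8 in Got-22, 74 and 192 in Tamm-2, 112 and 186 in Ull2-5, and 45 and 44 in Ag-0. In Omo2-3 it called 0, with 1697 loci at an unadjusted p under 0.05; limma on the Omo2-3 arrays alone also called 0, and limma with array quality weights 595. Fits of the other accessions on their own arrays called 2 in Bil-5, 0 in Eden-1 (1637 at an unadjusted p under 0.05 in the shared fit), 0 in Got-22 (2012), 3 in Tamm-2, 28 in Ull2-5 and 2 in Ag-0.

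Single arrays decided many of these calls. Of the 36 named changes within accessions, 29 lost their call when some array was left out. FMO1 and AT3G13610 in Eden-1, AT1G59950, AT1G26380 and AT5G45630 in Ull2-5, and AT2G25510 and AT2G43620 in Bil-5 kept theirs. Of these, several did not pass in limma on the arrays of their accession alone. They were FMO1 (adjusted p = 0.0943), AT3G13610 (0.235), AT5G45630 (0.0522), AT2G25510 (0.516) and AT2G43620 (0.162). Most of the other named changes ended in those fits too. All 6 named changes of Ag-0 ended without its dry replicate 3 (limma adjusted p between 0.310 and 0.406), all 6 of Tamm-2 without its dry replicate 3 and all 6 of Got-22 without its dry replicate 1. In Bil-5, LTP3, AT2G37870, AT4G33550 and PDF1.2A ended without dry replicate 1, and in Ull2-5, PnsB3, AT2G36145 and AT5G61160 without dry replicate 2. In Eden-1, NRAMP6 ended without wet replicate 3 (0.0540), CYP71A13 without wet replicates 2 or 3 or dry replicate 3 (up to 0.244), AT4G25790 without any of 21 arrays and AT2G37870 without any of 32. NDB3 in Got-22 kept its call without wet replicate 3, at -0.47. With array quality weights LTP3 (0.0508), LTP4 (0.0938), AT3G53980 (0.0942), MEE3 (0.0624) and AT5G39520 (0.0944) did not pass in Tamm-2, nor PDF1.2A in Bil-5 (0.0653), and centring on the median ended SAUR63 in Got-22 (0.0536).

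The counts moved with them. Bil-5 had 446 calls without its dry replicate 1, 367 without wet 1 and 1490 without dry 3, and Eden-1 40 without wet 2, 20 without dry 3 and 22 without wet 3. Got-22 had 1 without dry 1, 9 without wet 2, 6 without dry 3 and 34 without wet 3, and Omo2-3 8 without wet 1 and 5 without wet 3. Tamm-2 had 903 without dry 1, 33 without wet 1, 71 without wet 2 and 28 without dry 3, and Ull2-5 41 without dry 2, 47 without wet 2, 87 without dry 3 and 186 without wet 3. Ag-0 had 17 without wet 1, 55 without dry 2, 53 without wet 2 and 0 without dry 3, and 172 without Bil-5 dry 3 and 136 without Tamm-2 dry 3.

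Accessions nevertheless shared the direction of most drying changes. Across loci, drying changes of accessions correlated in each of the 21 pairs, from r = 0.155 (Omo2-3 and Ag-0) to 0.720 (Omo2-3 and Ull2-5), with a median of 0.550; no pair shares arrays, and loci are not independent replicates. Of the loci called in the other 6 accessions, the share with the same sign in the accession left out was 91.9% in Bil-5, 84.7% in Eden-1, 93.0% in Got-22, 89.2% in Omo2-3, 90.7% in Tamm-2, 88.5% in Ull2-5 and 77.6% in Ag-0.

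The interaction test called 6 loci. Reassigning dry and wet on residuals of the additive model called as many in 11 of 100 draws, the real one included. Chance thus cannot be excluded for this count as a whole. FMO1 changed by -3.26 ± 0.30 in Eden-1, from 8.06 on wet to 4.79 on dry arrays, and differed by -0.49 to 0.01 in the other 6, where its wet means were 4.09 to 4.52, near the array floor. A large fall could not be seen there, nor for AT1G66930, with wet means of 3.84 to 4.21 outside Tamm-2. Wet means of AT5G45000 were 4.22 to 4.39 in Bil-5, Eden-1, Omo2-3 and Ag-0, those of AT1G57630 at most 4.65 in Got-22, Omo2-3, Tamm-2 and Ag-0, and that of AT1G59950 3.70 in Got-22, which limits the falls that could be seen there too. AT5G45000 and AT1G57630, which encode proteins with a TIR domain of the kind found in immune receptors, changed by -1.75 ± 0.19 in Tamm-2 and by -1.58 ± 0.19 in Ull2-5; AT1G57630 also changed by -0.87 ± 0.19 in Bil-5. AT1G59950, of the aldo-keto reductases, changed by -3.28 ± 0.33 in Ull2-5 and -1.37 ± 0.33 in Tamm-2. AT1G66930, a protein kinase gene, changed by -0.70 ± 0.07 in Tamm-2, and AT5G58787, a RING-type gene, by -0.87 ± 0.14 in Ull2-5, while its difference was 0.29 ± 0.15 in Ag-0. In Tamm-2 the dry arrays of AT1G59950 and AT1G66930 lay near the floor, so the size of these falls is not exact. The SE and the F test use 1 spread per locus shared by all groups, those near the floor included. Values near the floor can vary less, so the SE can be too small and the F too large where there is signal. On the Eden-1 arrays alone the FMO1 change did not pass (limma adjusted p = 0.0943), while that of AT1G59950 on the Ull2-5 arrays alone did.

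Limma's adjusted interaction p was 0.00221 for FMO1, 0.0106 for AT1G66930, 0.0126 for AT1G59950, AT5G45000 and AT1G57630, and 0.0425 for AT5G58787. An unadjusted p under 0.05 was found at 1244 loci, where 1058.2 would be expected by chance. Leaving out a single array ended the calls of AT1G57630 (0.0939 without Ull2-5 dry replicate 2), AT1G66930 (0.0703 without Tamm-2 wet replicate 2), AT5G45000 (Tamm-2 wet replicates 1 or 2 or dry replicate 3, up to 0.129), AT1G59950 (Ull2-5 dry or wet replicates 2 or 3, up to 0.108) and AT5G58787 (any of 27 arrays, up to 0.136). Leaving out an accession without the largest change ended AT1G57630 (0.0552 without Got-22, 0.0503 without Eden-1), AT1G59950 (0.0809 without Got-22), AT5G45000 (0.0503 without Eden-1) and AT5G58787 (up to 0.430, without Eden-1), and AT5G58787 also ended with a trended robust prior (0.121) and without the lowest 25% of loci (0.0545). The count was 13 without Bil-5 dry replicate 3, 10 and 11 without Tamm-2 dry replicates 1 and 2, and 3 without Tamm-2 wet replicate 2 or Ull2-5 dry replicate 2; it was 99 with array quality weights, and without the 3 arrays of low quality weight 38 loci were called. Of the 23 list scores 0 passed the interaction test; the smallest permutation p was 0.0300 unadjusted and 0.689 adjusted, for dividing cells, the 1 list under 0.05 unadjusted.

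**Figure D3:**
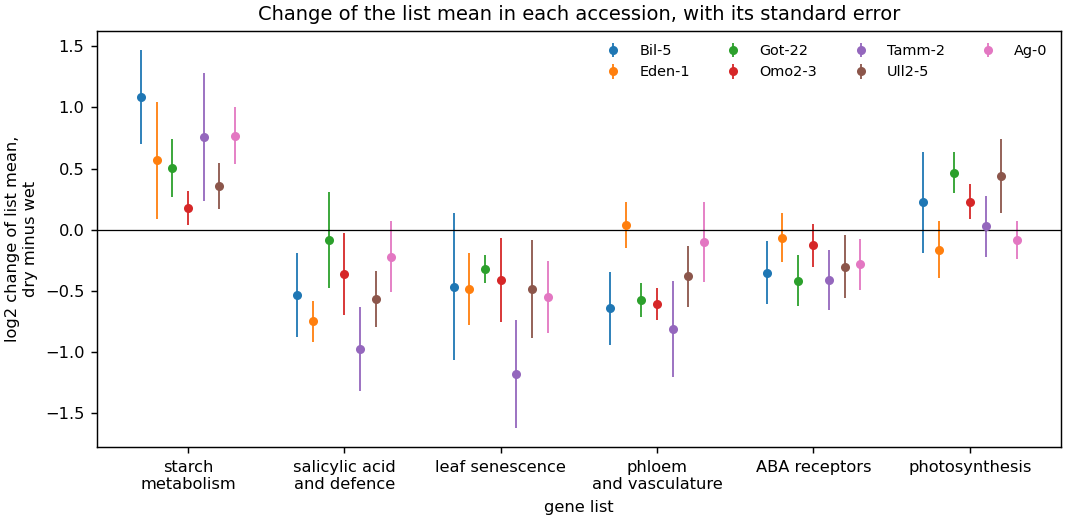
Change of the list mean (log2, dry minus wet, vertical axis) for 6 lists in each of the 7 accessions, with bars of 1 SE from the arrays of that accession (3 dry and 3 wet, or 2 and 3 in Ag-0). The starch list lies above 0 in all 7 accessions, from 0.18 in Omo2-3 to 1.08 in Bil-5.

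Several loci stood far apart between accessions, with QQS and AT4G29200 near the array floor in most of them. ESP, the epithiospecifier protein that directs glucosinolate breakdown to epithionitriles and nitriles, stood at 5.60 in Got-22 and between 11.33 and 12.58 in the other 6, while ESM1, its modifier, was highest in Got-22 at 12.10 against 5.79 to 8.49. QQS, a short gene that affects leaf starch content, stood at 9.41 in Eden-1 and 9.69 in Tamm-2 and at 4.27 to 5.29 elsewhere. AT4G29200 was at 9.28 in Eden-1 and at 4.39 to 4.48 elsewhere, AT5G26270 at 10.52 in Ag-0 against 5.78 to 6.02, and AT1G56300 at 5.08 in Ull2-5 against 9.08 to 9.65. Limma's adjusted p was 7.47e-20 for ESP, 2.71e-10 for ESM1 and 4.79e-20 for QQS.

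Other loci were among the smallest p-values of the accession test. The TIR-type receptor genes AT4G16920 and AT1G63880 stood at 10.20 in Tamm-2 and 7.33 in Omo2-3, with 4.11 in Bil-5 and 3.85 in Eden-1 as their lowest means. AT1G50290 was lowest in Tamm-2 (4.32) and Eden-1 (4.36), AT3G19520 in Ag-0 (4.29) and Eden-1 (4.32), and AT1G63830 in Eden-1 (6.24, against 9.08 to 9.31). AT4G19470 stood at 7.01 in Ag-0 and AT1G36020 at 6.36 in Eden-1, against 4.06 to 4.17 and 3.91 to 4.05 elsewhere. The range of the 7 means was 4.23 for AT1G65370, 2.33 for AT5G03440 and 2.54 for G6PD4, of the oxidative pentose phosphate pathway family. The means of 3.85 to 4.36 given here lay near the array floor, so differences from them are not exact in size.

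Against the mean of the other 6, HCHIB, a basic chitinase, was higher by 4.98 ± 0.35 in Eden-1, where AT2G25510 and DR4 lay at -4.87 ± 0.49 and -4.23 ± 0.37. AT4G21640, a subtilase gene, was higher in Got-22 by 3.95 ± 0.22, and AT2G41090 lay at -6.03 ± 0.25 there. AT2G25450 and AT1G63880 were higher in Omo2-3 by 3.24 ± 0.38 and 2.91 ± 0.13, and AT5G38980 and AT2G25510 lay at -5.30 ± 0.48 and -5.06 ± 0.49. AT5G38980 lay at -5.47 ± 0.48 in Tamm-2. In Ull2-5, AT2G25510 and AT1G59950 were higher by 4.71 ± 0.49 and 3.67 ± 0.18, and AT1G51430 lay at -3.09 ± 0.21. In Ag-0, AT2G25510 was higher by 4.81 ± 0.53, and PDF1.2A and AT3G62550 lay at -4.56 ± 0.93 and -4.39 ± 0.31. AT2G15555 and AT1G72920 were higher in Bil-5 by 3.57 ± 0.48 and 3.36 ± 0.31, and AT3G48640 lay at -3.25 ± 0.52, but the arrays of Bil-5 differed at all 3. AT2G15555 read 4.77 on dry replicate 3 and 10.17 to 11.80 on its other arrays, AT1G72920 4.18 on dry replicate 2 and 7.32 to 9.25 on the others, and AT3G48640 4.81 to 10.65. The sizes of several of these differences are not exact: AT1G72920, AT4G21640, AT1G63880 and AT1G59950 lay near the array floor in most other accessions, HCHIB in Got-22 and Tamm-2, AT2G25510 in Eden-1, Got-22 and Omo2-3, AT5G38980 in Omo2-3 and Tamm-2, and PDF1.2A in Ag-0.

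FLC, the repressor of flowering that vernalization silences, was high in 6 accessions, between 9.70 in Got-22 and 11.01 in Eden-1, and averaged 6.81 in Bil-5 (limma adjusted p = 2.75e-06). The Bil-5 arrays differed among themselves, with 4.28, 6.73 and 8.39 on wet and 9.13, 8.07 and 4.26 on dry arrays. FLC differed between dry and wet by 0.04 ± 0.28 (limma adjusted p = 0.941). SOC1, a flowering promoter repressed by FLC, ranged from 4.35 in Ull2-5 to 7.55 in Tamm-2, and MAF5 stood at 5.81 in Ag-0 against 3.83 to 4.17. The lowest means of both lay near the array floor, so these differences are not exact in size. FRI was at 4.52 to 4.60 in all 7, near the floor of the array (limma adjusted p = 0.814).

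**Figure D4:**
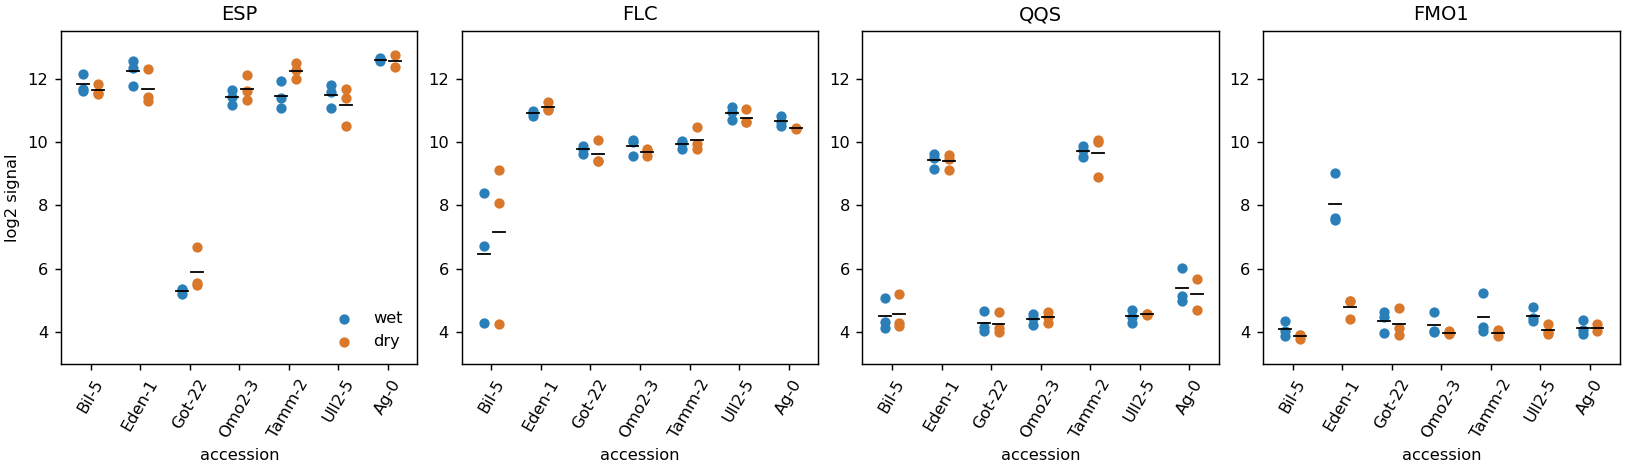
Log2 signal (vertical axis) of ESP, FLC, QQS and FMO1 on each of the 41 arrays, by accession, with wet arrays in blue, dry arrays in orange and a short line at each group mean. ESP is low in Got-22, QQS is high in Eden-1 and Tamm-2, FMO1 falls in Eden-1 under drying, and the Bil-5 arrays of FLC run from 4.26 to 9.13.

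Limma called 6635 loci for the accession effect (31.4%), 1797 of them with means that ranged over at least 1 log2 unit and 348 over at least 2. Against the other 6 accessions, 2259 loci were higher and 1712 lower in Eden-1, 474 and 479 in Bil-5, 837 and 815 in Got-22, 672 and 1022 in Omo2-3, 758 and 900 in Tamm-2, 1013 and 677 in Ull2-5, and 393 and 351 in Ag-0. Of the called loci, 2376 were also called for drying, where independent lists would share 1575.04; both tests use the same arrays and the same spread. Salicylic acid and defence genes were called more often than other loci (17 of 23, 21 adjusted over the list alone; Fisher's exact test, odds ratio 6.22, adjusted p = 0.00077), with PR1 ranging over 5.24 log2 units and PR2 over 4.93. Photosynthesis genes were called less often (2 of 30, 1 adjusted over the list alone, with odds ratio 0.156 and adjusted p = 0.0279), and the other 21 lists did not pass. Fisher's test treats loci as independent, but list members vary together (camera's estimated correlation 0.31 for defence and 0.81 for photosynthesis). Its p-values can thus be too small. The defence list mean in Eden-1 was 8.37 on dry and 9.12 on wet arrays, against 6.61 to 7.88 elsewhere, so 1 accession can carry many calls. With array quality weights the accession count was 10129, and on wet arrays alone it was 3114.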

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

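Of the splits below, those made after removing the drying effect were chosen after the result was seen. The drying change of 6 loci differed between accessions by limma's interaction test: FMO1 (adjusted p = 0.00221), AT1G66930 (0.0106), AT1G59950 (0.0126), AT5G45000 (0.0126), AT1G57630 (0.0126) and AT5G58787 (0.0425). Reassigning dry and wet within accessions gave as many as 6 interaction loci in 11 of 100 draws, the real one included, with 22 as the highest of the other draws. That test decides nothing, since relabelling some accessions turns the drying effect itself into a difference between accessions. Made on residuals of the additive model, which hold no drying effect, the reassignments gave as many as 6 in 11 of 100 draws, the real one included, with 30 as the highest other, so chance cannot be excluded for this count as a whole. The draws on the full values called at most 1 locus for the drying effect, against 5024 in the real assignment (1 of 100 draws as large). Reassigning arrays to accessions called at most 43 against 6635 (1 of 100). This is the smallest share that 100 draws can give, and chance assignment as the source of either whole count is unlikely. Real differences add to the spread in these draws, so the draws do not show how many single calls came by chance.

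Within single accessions 3 dry and 3 wet arrays make 10 splits, too few for a share under 0.05. The real split called 888 loci in Bil-5 and the highest other 493, and the corresponding counts were 63 and 7 in Eden-1, 20 and 5 in Got-22, 266 and 6 in Tamm-2, and 298 and 1 in Ull2-5. In each of these 5 accessions 1 of the 10 splits, the real one, reached the real count, and in Omo2-3, with 0 called and 2 in the highest other split, all 10 did. Ag-0 has 2 dry arrays and was not split.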

How the results depend on the processing

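No called value changed sign under any setting; 55 values of 10 genes or lists that were not called, FLC and RD29A among them, did. Counts of every comparison stayed within 1.5 times under quantile normalization, median centring, removal of the lowest 25% of loci and a trended robust prior. For settings below, the cause was not tested except where fewer arrays, accessions or loci pass by construction. A log2 filter of 0.5 left 654 rises and 627 falls. With array quality weights the drying calls were 1962 in Bil-5, 359 in Eden-1, 142 in Got-22, 595 in Omo2-3, 37 in Tamm-2, 839 in Ull2-5 and 255 in Ag-0, with 99 interaction and 10129 accession loci. Without the 3 arrays of quality weight under 0.5, chosen after seeing the data, they were 122 in Eden-1, 47 in Got-22, 2 in Omo2-3, 73 in Tamm-2, 540 in Ull2-5 and 303 in Ag-0, with 38 interaction loci. Fits on 1 accession alone, with fewer degrees of freedom, called 2 in Bil-5, 0 in Eden-1, 0 in Got-22, 3 in Tamm-2, 28 in Ull2-5 and 2 in Ag-0. The interaction count was 13 without Bil-5, 2 without Eden-1 and 3 without Got-22. The accession count was 3114 on wet arrays only and 1797 with a range of at least 1. Camera called 0 lists with an estimated correlation, 9 without Omo2-3, 8 without Ull2-5 and 4 without Got-22, against 5.

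Replicate numbers did not pair the arrays in every accession: 10 of 20 pairs of dry and wet arrays correlated over 0.1 in their deviations and 6 below -0.1, 7 dry arrays correlated best with their own number, and 0 loci had a number effect. The 6 lay in Bil-5, Got-22 and Omo2-3. Pairs of Eden-1, Tamm-2, Ull2-5 and Ag-0 all correlated positively (0.0904 to 0.544), and each Ull2-5 dry array correlated best with its own number. Pairing in these accessions stays open. With number as a replicate block 2554 loci rose and 2442 fell, and no count moved by over 1.5 times. With blocks within accessions Got-22 had 11, Omo2-3 1 and Ag-0 21 calls, and the interaction 3. Of the 6 named interaction calls 5 ended, all but AT5G45000, with FMO1 at a limma adjusted p of 0.131. These blocks also ended all 6 named changes of Ag-0, and AT3G53980, AT5G45630, SAUR63 and NDB3 in Got-22. Others ended were AT4G25790 and CYP71A13 in Eden-1, AT3G53980, MEE3 and AT5G39520 in Tamm-2, and PnsB3 and AT2G36145 in Ull2-5.

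Leaving out each array gave 2315 to 2867 rises, 2205 to 2600 falls, 5920 to 7446 accession loci, 3 to 13 interaction loci and 5 to 8 lists; a lone dry Ag-0 array is then assumed to vary like other groups. Of named calls, 10 of 99 for drying and 9 of 111 for accession ended in some such fit. Calls within accessions ranged over 367 to 1490 in Bil-5, 20 to 79 in Eden-1, 1 to 34 in Got-22, 0 to 8 in Omo2-3, 28 to 903 in Tamm-2, 41 to 418 in Ull2-5 and 0 to 172 in Ag-0. The list count was 8 without Tamm-2 dry replicate 2. Over all such fits and results 13063 values kept their call or count, 425 lost and 83 gained. Array signal near the floor limits what a loss of expression can show, since a silent locus and a poorly hybridising one read alike.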

Other observations

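Of the tests below, those on noisy arrays, on arrays of another accession, on drying in Bil-5, on mismatches and on time of day, the setting without 3 arrays, and the list scores without Bil-5, were chosen after the data were seen. Of 26 glucosinolate genes 2 rose and 3 fell (camera adjusted p = 0.483), among them UGT74C1 (0.37 ± 0.08) and the regulator MYB51 (-0.55 ± 0.13), which lost its call without Tamm-2 (limma adjusted p = 0.0612). Of 19 flowering time genes 1 rose, LD (0.19 ± 0.06), and 0 fell (camera adjusted p = 0.961). Of 20 genes of anthocyanin and flavonol synthesis 1 rose, the regulator PAP1 (0.36 ± 0.12), and 1 fell, the chalcone isomerase CHI (-0.52 ± 0.15, with limma adjusted p = 0.0544 without Got-22; camera adjusted p = 0.848). Of 13 heat shock and chaperone genes 1 rose and 2 fell, HSP90.1 changing by -1.13 ± 0.25 and the small heat shock gene HSP21 rising by 0.21 ± 0.07 near the floor (camera adjusted p = 0.848); the permutation of array scores did not call this list (adjusted p = 0.0685) but did without Bil-5 (0.0271). Adjusted over the list alone, 0 flowering genes passed and 0 and 1 anthocyanin genes rose and fell. LD lost its call without any of 10 arrays (limma adjusted p up to 0.0677) or any of 5 accessions (up to 0.108, without Ag-0). PAP1 and HSP21 lost it without Ag-0 dry replicate 2 (0.0550 and 0.0615) or Bil-5 dry replicate 1, and without some accessions (up to 0.0931 and 0.0789, both without Bil-5).

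Of 19 genes of touch, wounding and handling 4 rose and 0 fell (camera adjusted p = 0.124), led by DREB2A (0.72 ± 0.15), TCH2 (0.39 ± 0.09) and ERF4 (0.37 ± 0.09).

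The Bil-5 arrays differed among themselves at loci that separate the other accessions. Besides FLC, AT2G25510 read 4.61 on dry replicate 3 and 11.09 to 13.16 on the other Bil-5 arrays, and AT5G38980 read 4.29 on wet replicate 1 and 10.28 to 11.37 on the others. Over 500 loci chosen without Bil-5, its arrays correlated at a mean r of 0.534. In the other 6, each at its own 500 loci chosen without it, the mean r was 0.759 to 0.897. Drying that was alike in all pots of a treatment does not account for this. Bil-5 arrays of the same soil water correlated at these loci at a mean r of 0.519 (95% bootstrap interval 0.449 to 0.592), against 0.768 or more in the other 6. An earlier test of drying took the 314 loci that ranged over at least 3 log2 units in Bil-5. Dry and wet arrays lay apart at 72 of them, where 3 against 3 arrays have a 10% chance of it. That test was set aside, since only 16 of its loci were among the 500. Uneven drying of the Bil-5 pots stays open. On dry replicate 3 AT3G53980 read 8.81, against 12.23 and 12.16 on the other dry arrays and up to 8.80 on wet ones. AT4G33550 read 5.14 there, against 9.37, 9.96 and up to 5.86, though DAA1 stayed high (6.67, at most 4.32 on wet). A whole array of one of the other 6 accessions does not account for the spread either. No Bil-5 array correlated above 0.449 with another accession, where arrays of the other 6 matched their own at 0.788 or more. Mixed samples were not tested. Arrays of accessions not analysed here were not compared and stay open, as do noisy arrays, since spread in Bil-5 was raised at the separating loci only 1.14 times (95% bootstrap interval 1.08 to 1.21) as much as at all others, under the 1.5 set as a limit. A candidate explanation that also stays open is more than 1 genotype among the Bil-5 plants: separating loci that lie 4 to 200 loci apart differed together, with a mean squared correlation 0.0163 above that of loci on different chromosomes (permutation p = 0.0055), and the largest such excess in the other 6 accessions was 0.00594.

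Some loci lay at least 2 log2 units from every other accession in 1 accession alone. A mismatch in that accession alone lowers its signal, and 80% lower was set by hand as the limit for it. Of the 42 such loci 17 were lower and 25 higher, or 40.5% lower (exact 95% interval 25.6 to 56.7), which argues against mismatches in that accession alone as the whole cause. The limit was first set for mismatches of any kind, which was wrong by design, since a mismatch shared by the other 6 leaves the remaining accession higher. Mismatches shared by the other 6 or at single loci such as ESP stay open, as do deletions and differences in expression, which were not tested.

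Under drying 11 of 14 starch genes rose, and 12 of 23 salicylic acid and 6 of 14 senescence genes fell, though camera with an estimated correlation called none of the 3 lists (adjusted p = 0.277 for each). A harvest of dry pots at another time of day was assumed to move the core clock genes as much. The median absolute change of the 7 measured (CCA1, LHY, PRR5, PRR7, TOC1, GI and ELF4) was 0.12 (95% bootstrap interval 0.10 to 0.36), against a median starch change of 0.56 (0.40 to 0.87). These are means over accessions, in which opposite shifts cancel. The mean of the full clock list changed by 0.29 in Eden-1, without overlap of dry and wet arrays, and by -0.13 in Tamm-2, with overlap. A shift in single accessions stays open. Of 17 clock genes 2 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.968), PRR3 rising by 0.49 ± 0.11 and PRR5 changing by -0.46 ± 0.13 (lost without Tamm-2, Ag-0 or Ull2-5; limma adjusted p up to 0.0744). Without the 3 arrays of lowest quality the starch mean was still 0.60 (0.39 to 0.81 at 2 SE), so these arrays do not account for it. The drying treatment itself remains a possible explanation, and which step links it to these genes was not tested.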
